A study of Rattus norvegicus with 4 samples.

How the data were processed

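Total RNA from the pons and medulla of male Wistar pups was labelled with Cy3 and hybridised to 1-colour Agilent rat arrays, per the labels' protocols, with 4 arrays in 4 groups of 1. The scanner files hold background-corrected signal intensities per spot, made by the authors with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes, and the file headers name the rn4 build for probe positions. The authors also deposited a table of normalized log2 values for the same arrays. Set against the scanner intensities, its values are log2 signals shifted by the 75th percentile of each array and centred on the median of each probe across the arrays. The shift matched the table's values before centring to within 0.00015, their direction is that of the signal, and its column medians were 0.03, -0.01, 0.01 and -0.02. It served as an alternative.

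Levels were computed as log2 of the processed signal. Control spots and spots flagged as outliers (between 266 and 470 per array) were left out, spots of a probe were averaged, and the 75th percentile over all 45598 non-control probes was subtracted on each array. A probe counted as well above background when at least 50% of its spots carried that flag. Of the probes, 31726 were named through the gene identifier in the files, 449 through an accession matched without version to the RefSeq gene table of the GRCr8 assembly and 4077 by the symbol in the files. The other 9346 had no gene name here. For 7858 of 25623 genes with more than 1 probe, the probe with the highest mean represented the gene. Exon and UTR positions were not used here.

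The LPS and poly I:C main effects were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, an additive term for each treatment, 1 residual degree of freedom, prior degrees of freedom 2.21), two-sided, with Benjamini-Hochberg adjustment over 17906 genes well above background on at least 2 arrays. The spread in this fit is the difference between the LPS effects of the dam groups, so it holds animal variation, noise and any true interaction, and since nothing says that the arrays came from separate litters, p-values measure only the spread between these arrays. The fit was tested on simulated data for the LPS main effect with 17906 genes, of which 200 were changed, in 20 runs. The simulated noise was normal and independent between genes, with variances drawn from the fitted prior and without interaction or tissue differences. The rates below therefore hold under the assumptions of the fit and were not shown for these arrays. It recovered 0.8% of genes changed by 1 on the log2 scale, 79.6% of those changed by 2, 96.9% by 4 and 99.2% by 8, with 7.65 false among 146 calls per run. Comparisons of 1 array with 1 array have no test, and genes at least 2-fold apart were counted among those well above background on both arrays. A gene with no probe well above background on an array has only a bound there. It was computed against the higher of its own signal and the lowest signal well above background on that array, between -5.17 and -4.95 on the log2 scale. This floor replaced a lower one, the lowest probe mean, after the bounds had been seen, and it makes the bounds smaller. The limma fit and the list medians use the signals as measured, also where they are not well above background.

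The 32 gene lists covered immune pathways, stress and cell types that a dissection of hindbrain could hold. They were fixed before the data were examined, as were the tests of treatment effects, the rule for named genes and the alternatives below. Tests of explanations that use choroid plexus, meningeal and blood vessel markers were chosen after the results were seen. The restriction to genes within 0.5 log2 on both PBS pup arrays was added after the data were seen. Of 768 members, 752 matched a gene. A list's median log2 difference was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. For the LPS main effect, 7.5% of 200 simulated lists without a shift fell outside the central 95% of random lists, and 100% of those shifted by 0.3 lay above it, over 17906 genes. The simulated lists were drawn at random from the same genes. Their rates therefore do not hold for lists whose members vary together between arrays. Lists overlap in some members, such as Lcn2 and Gbp2, and markers in whole tissue do not give a cell type's share. Genes were named only with a symbol that is not a placeholder. For LPS these were the 12 largest mean rises and falls among genes past the threshold, on all 4 arrays and at least 2-fold in both dam groups, filled by mean change where fewer passed, and the 8 largest bounds. For poly I:C they were the 10 highest and 10 lowest by the smaller of the PBS pup and LPS pup differences, for the difference of LPS effects the 10 at each end, and for lists up to 4 members with the largest mean change in the comparison described. Of these, 1 gene for poly I:C and 1 for the difference of LPS effects are not described here. Cxcl1 and Icam1 are set in other comparisons than the one that named them.

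Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the authors' table, no filter on dim probes, well above background on all 4 arrays, the median of a gene's probes, outlier spots kept, a 1.5-fold threshold, no term for the other treatment, a trended and robust variance prior, a 2-fold threshold beside the adjusted p, and each array left out. All 4 arrays lie on 1 slide and carry 1 scan time, so slide and scan could not act as batches. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used beside R.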

Results

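Gene expression in the pons and medulla of male Wistar rat pups was measured on 4 Agilent 1-colour arrays, with 1 array for each of 4 groups. Pregnant dams had received an intraperitoneal injection of 10 mg/kg poly I:C, a synthetic double-stranded RNA that mimics viral infection, or of the vehicle PBS on gestational day 10. On postnatal day 11 their pups received 0.25 mg/kg LPS, a bacterial cell wall component that activates toll-like receptor 4, or PBS, and tissue was taken 4 hours later. The groups were PBS dam and PBS pup, PBS dam and LPS pup, poly I:C dam and PBS pup, and poly I:C dam and LPS pup. Nothing in the labels said how many pups stood behind an array, so no group had a replicate. Of 58717 non-control spots per array, between 71.5% and 73.9% were well above background, and 0 were saturated. The median SD of log2 signal between spots of the same probe lay between 0.0496 and 0.0536, and this technical spread leaves out differences between animals. All levels are log2 signals minus the 75th percentile of the array, and the number of arrays limits the precision of every value.

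The first comparison asked which genes responded to LPS whatever the dam had received. LPS raised chemokine genes, interferon-stimulated genes and genes of NF-kB feedback and endothelial adhesion. Cxcl10 and Cxcl11, which attract activated T cells, were not well above background on either PBS pup array, and Cxcl10 was at least 859-fold higher after LPS in pups of PBS dams and at least 812-fold higher in pups of poly I:C dams (adjusted p = 0.0139). Cxcl11 was at least 164-fold and 138-fold higher (adjusted p = 0.0139), and Selp, the P-selectin of activated endothelium, was at least 167-fold and 102-fold higher (adjusted p = 0.0142). Isg15, a ubiquitin-like interferon product, rose 40.4-fold (log2 5.34 ± 0.09, SE, adjusted p = 0.0208), and the interferon-inducible GTPase Gbp2 rose 36.8-fold (SE of log2 0.11, adjusted p = 0.0295). In limma's additive model of both treatments, with 2 arrays per arm, 30 of 17906 genes rose and 1 fell at an adjusted p under 0.05.

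Further genes past the threshold and well above background on all 4 arrays were Bcl3, a nuclear regulator of NF-kB, with a rise of 30.3-fold (log2 4.92 ± 0.11), Ifit2 with 23.6-fold, the apoptosis inhibitor Birc3 with 18.4-fold, the interferon regulatory factor Irf7 with 18.3-fold and Usp18, which removes Isg15 from proteins, with 16.3-fold. Herc6 rose by 3.91 on the log2 scale, Apol9a 12.4-fold, the cytokine gene Tnf 10.2-fold, Oas1a 10.1-fold and the uridine phosphorylase gene Upp1 9.80-fold. Their adjusted p ranged from 0.0315 for Bcl3 to 0.0396 for Ifit2. Cxcl9 was well above background on both LPS arrays and neither PBS array, at least 19.7-fold higher in pups of PBS dams and at least 16.2-fold in pups of poly I:C dams (adjusted p = 0.0295). Of the 30 genes that rose, 15 were well above background on all 4 arrays, and 14 on both LPS arrays and neither PBS array. The probes of Cxcl10 and Isg15 lie on chromosome 14 from 17267994 to 17268053 and on chromosome 5 from 173034674 to 173034733, in the rn4 build that the files use. Among the genes with the largest bounds, those that did not pass the test were Ifit3 (at least 49.6-fold and 36.8-fold in the PBS and poly I:C dam groups, adjusted p = 0.139), Tnfsf10 (21.3-fold and 32.9-fold, adjusted p = 0.0530), Ubd (33.3-fold and 20.9-fold, adjusted p = 0.0721) and Cxcl1 (69.1-fold and 9.42-fold, adjusted p = 0.237).

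The 1 gene that fell was Srms, a kinase gene named after its values were seen, which fell by 3.19 on the log2 scale (SE 0.10, adjusted p = 0.0364) and was well above background on 3 arrays. Its levels on the LPS arrays of the PBS and poly I:C dams were -4.69 and -5.07. The lowest signals well above background there were -5.09 and -5.17, so the size of the fall is not exact. No gene measured on all 4 arrays fell past the threshold, so the 12 genes at least 2-fold lower in both dam groups are given without a call. Slc40a1, the iron exporter ferroportin, was 2.99-fold lower after LPS in pups of PBS dams and 2.55-fold lower in pups of poly I:C dams (adjusted p = 0.124). The endothelial nitric oxide synthase gene Nos3 was 2.12-fold and 2.15-fold lower, the organic anion transporter gene Slco1a4 2.07-fold and 2.21-fold, and the carbonic anhydrase gene Car4 2.80-fold and 2.34-fold. Srarp was 2.94-fold and 3.42-fold lower, C13h1orf115 3.24-fold and 2.90-fold, Ushbp1 3.14-fold and 2.48-fold, and the endothelin gene Edn3 2.82-fold and 2.43-fold. Cyyr1, Prom1, Ctla2a and Il16 had mean differences of -1.20, -1.13, -1.08 and -1.05 on the log2 scale. The adjusted p of these 12 genes ranged from 0.0879 to 0.147.

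The count depended on the settings. The pair given last here, for genes within 0.5 log2 on both PBS pup arrays, does not tell how many called genes meet that restriction. Srms, the gene that fell, met it, at -1.59 and -1.79 on the PBS pup arrays of the PBS and poly I:C dams. With 1 array left out no residual is left unless the term for the other treatment is dropped too, which on all 4 arrays gave 76 rises and 10 falls, so both changes enter the next counts. It was 1 rise without the PBS dam and PBS pup array, 1 without the PBS dam and LPS pup array, 4 without the poly I:C dam and PBS pup array and 33 without the poly I:C dam and LPS pup array (13 of them among the 31 genes of the full fit), each with 0 falls, against 318 rises and 70 falls with normexp background correction, 220 and 50 with a trended and robust variance prior, 0 and 0 with no filter on dim probes and 9 and 0 among genes within 0.5 log2 on both PBS pup arrays.

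Of 43 measured interferon-stimulated genes, 9 rose over all genes tested and 38 rose when adjusted over the list alone, with a median difference of 2.03 in pups of PBS dams and 1.79 in pups of poly I:C dams. Of these genes 36 and 37 were well above background on both arrays of the dam group, and with bounds for the others the medians were 1.74 and 1.61. Gbp5, at 4.98 and 4.33, missed the threshold over all genes (adjusted p = 0.0530). Of 30 cytokines and chemokines, 5 rose over all genes and 20 adjusted over the list alone, with medians of 1.77 and 1.35. Of these 19 and 21 were well above background on both arrays, and with bounds the medians were 1.58 and 1.23. In that list Il1b was 5.06 and 4.09 log2 higher (adjusted p = 0.0955), Ccl3 2.77 and 1.45 higher, and Il1rn, the interleukin-1 receptor antagonist, 1.65 and 1.26 higher. Of 17 genes of MHC class I antigen processing, 0 rose over all genes and 9 rose adjusted over the list alone, with medians of 0.86 and 1.07 in the PBS and poly I:C dam groups. Member by member, 13 of the 17 had the smaller LPS difference in pups of poly I:C dams, with a median difference of LPS effects of -0.11. Nlrc5, the transactivator of this pathway, was 3.05 and 2.63 higher, and the immunoproteasome genes Psmb9 and Psmb8 were 2.90-fold and 2.82-fold, and 6.29-fold and 3.05-fold, higher. The 8 MHC class II genes had medians of 0.24 and -0.06, with 0 changed by either adjustment. With normexp background correction they were 0.02 and 0.01, and with bounds the second was -0.18.

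Of 19 NF-kB targets and feedback genes, 2 rose over all genes, Bcl3 and Birc3, and 10 rose adjusted over the list alone, with medians of 0.69 in pups of PBS dams and 0.37 in pups of poly I:C dams. Of 24 STAT3 and acute phase genes, 0 rose over all genes and 14 adjusted over the list alone, with medians of 0.74 and 0.55. Its members Socs3, a feedback inhibitor of cytokine receptors, and Lcn2, an iron-binding acute phase protein, were 3.84 and 2.70, and 3.55 and 2.59, higher. Of 26 glucocorticoid-responsive genes, 0 rose over all genes and 16 adjusted over the list alone, with medians of 0.98 and 0.54. The metallothionein genes Mt1 and Mt2A in that list were 3.85 and 2.07, and 3.36 and 2.35, higher. Of 22 endothelial activation genes, 2 rose over all genes, while 11 rose and 1 fell adjusted over the list alone, with medians of 0.82 and 0.46. Ch25h, which makes 25-hydroxycholesterol, Ptgs2, the inducible cyclooxygenase, and the adhesion molecule Icam1 were 4.43 and 2.54, 3.73 and 2.70, and 3.96 and 2.16 higher. Of 22 toll-like receptor and inflammasome components, 0 rose over all genes and 10 adjusted over the list alone, with medians of 0.51 and 0.44, or 0.48 and 0.35 with bounds, and the LPS co-receptor gene Cd14 was 2.99 and 1.90 higher. Of 25 immediate early genes, 9 rose adjusted over the list alone and 0 over all genes, with medians of 0.27 and 0.25. Each of these 9 lists with a rise by either adjustment had a median above all 10000 random lists matched on expression in both dam groups. Normexp background correction gave smaller medians in pups of PBS and poly I:C dams, 0.86 and 0.71 for interferon-stimulated genes, 0.68 and 0.45 for cytokines and chemokines, 0.47 and 0.34 for MHC class I, 0.31 and 0.22 for NF-kB targets and 0.45 and 0.27 for STAT3 and acute phase genes. It gave 0.74 and 0.31 for glucocorticoid-responsive genes, 0.54 and 0.27 for endothelial activation, 0.10 and 0.17 for toll-like receptor and inflammasome components and 0.18 and 0.15 for immediate early genes.

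The list medians of microglia and astrocyte markers lay near 0 after LPS, though single members of the resident cell lists were lower. The medians in pups of PBS and poly I:C dams were -0.12 and -0.05 for 25 microglia markers and -0.06 and -0.04 for 18 astrocyte markers, with 0 members changed by either adjustment, and the first astrocyte value was 0.01 with quantile normalization. Among microglia markers, Gpr34 was 2.15-fold and 1.46-fold lower and the purinergic receptor P2ry12 1.73-fold and 1.46-fold lower in the PBS and poly I:C dam groups. Of 19 endothelial and pericyte markers, 0 changed over all genes and 5 fell adjusted over the list alone, 2 members were at least 2-fold lower in pups of PBS dams, and the medians were 0.02 and -0.07, the first being -0.03 with normexp background correction and -0.02 with median scaling. The tight junction gene Cldn5 was 1.28 and 0.78 lower. Of 25 reactive astrocyte genes, 2 rose over all genes and 8 adjusted over the list alone, with medians of 0.82 and 0.28, or 0.25 and 0.15 with normexp background correction. The 2 were Cxcl10 and Gbp2, which also belong to the cytokine and the interferon list, so they are not a separate finding. The 20 pan-neuronal markers had medians of -0.03 and 0.03, the first being 0.02 with quantile normalization, and 17 housekeeping genes had medians of -0.05 and -0.02, the first being 0.01 with quantile normalization. Of the housekeeping genes 1, the transferrin receptor gene Tfrc, fell adjusted over the list alone and 0 over all genes. Beside the inflammatory lists, markers of other tissues differed on the same arrays. Of 18 choroid plexus and ependymal markers, 1 rose over all genes, Kl, and 2 adjusted over the list alone, with medians of 1.67 and 0.51, the first being 1.48 with bounds, and 0.53 and 0.19 with normexp background correction. Of 10 neutrophil and monocyte markers, 0 rose over all genes and 3 adjusted over the list alone (S100a8, S100a9 and Plac8), with medians of 2.94 and 0.25, or 1.053 and 0.09 with normexp background correction. Of 17 meningeal and fibroblast markers 0 changed by either adjustment, with medians of 0.83 and -0.26.

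**Figure D1:**
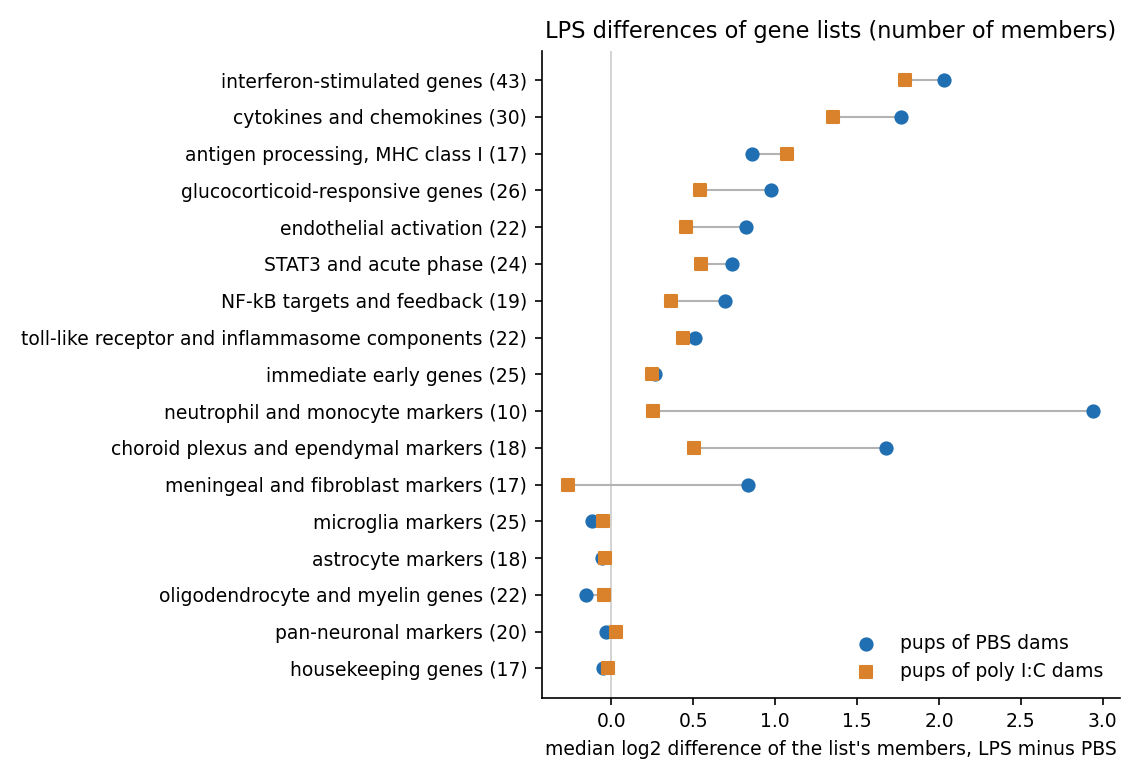
Median log2 difference between LPS and PBS pups for 17 of the gene lists, with circles for pups of PBS dams, squares for pups of poly I:C dams and the number of measured members in brackets. Interferon-stimulated genes lie at 2.03 and 1.79, and neutrophil and monocyte markers at 2.94 and 0.25. Each group was 1 array, so no error bar can be drawn.

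In pups of PBS dams, the LPS array showed higher inflammatory genes together with much higher choroid plexus, meningeal and neutrophil genes. Ttr, the transthyretin gene of the choroid plexus, was 9.31 log2 higher (a 634-fold difference), and the median of 18 choroid plexus and ependymal markers was 1.67 higher. Sostdc1 and Folr1 of this list were 4.03 and 3.57 higher. The 17 meningeal and fibroblast markers had a median of 0.83, led by Mgp at 2.24 and Slc13a4 at 1.97, and 10 neutrophil and monocyte markers a median of 2.94, with S100a9, Np4 and S100a8 at 3.96, 3.85 and 3.38. Of 17010 genes well above background on both arrays, 301 were at least 2-fold higher and 61 at least 2-fold lower after LPS. A further 139 and 38 genes were well above background on 1 of the arrays and had a bound of at least 2-fold higher or lower. With 1 array per group this difference has no replicate check and no p-value. Normexp background correction left 126 higher and 6 lower, and among genes within 0.5 log2 on both PBS pup arrays, a restriction chosen after the choroid plexus markers were seen, 199 were higher and 40 lower.

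In pups of poly I:C dams, the inflammatory genes were also higher after LPS, while the meningeal markers were not. Isg15 was 40.6-fold higher, Gbp2 34.1-fold and Bcl3 32.9-fold. The median of the meningeal and fibroblast markers was -0.26, with 3 of 17 members higher. The choroid plexus and ependymal markers had a median of 0.51, with Ttr 2.67 higher, and the neutrophil and monocyte markers a median of 0.25, with S100a9 and S100a8 at 2.32 and 2.54 and the defensin gene Np4 at -0.60. Of 17401 genes measured on both arrays, 188 were at least 2-fold higher and 51 at least 2-fold lower, and 121 and 60 more had a bound of that size. Normexp background correction left 80 higher and 4 lower, and the restriction to genes within 0.5 log2 on both PBS pup arrays 134 and 23.

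The LPS differences of the dam groups rest on separate arrays. Among 16843 genes well above background on all 4 arrays, 295 were at least 2-fold higher in pups of PBS dams, 162 in pups of poly I:C dams and 124 in both, against 2.84 for independent lists. The corresponding counts of lower genes were 58, 45 and 12, against 0.155. Across genes, which are not independent replicates, Pearson's r was 0.519 and Spearman's rho 0.139.

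**Figure D2:**
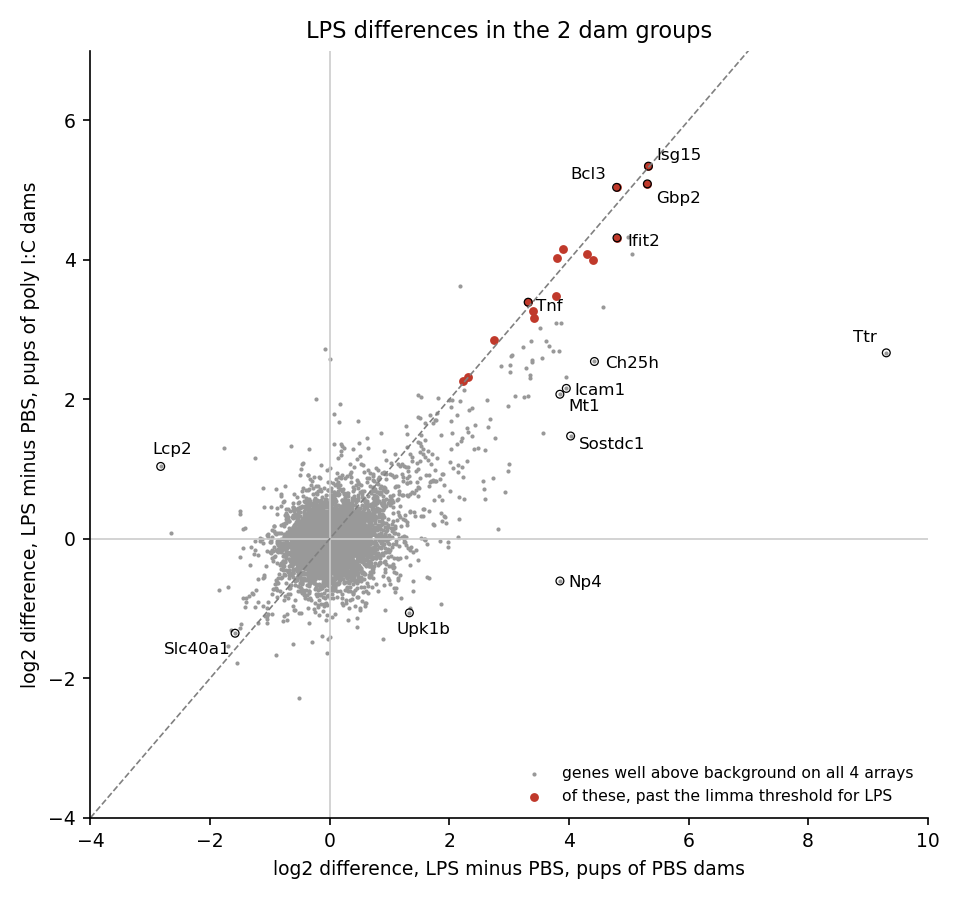
Log2 difference between LPS and PBS pups of PBS dams (horizontal axis) and of poly I:C dams (vertical axis) for the 16843 genes well above background on all 4 arrays. Red points passed the limma threshold for the LPS main effect, the dashed line marks equal differences, and Isg15 lies at 5.33 and 5.35, Icam1 at 3.96 and 2.16 and Ttr at 9.31 and 2.67.

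The next comparison asked which genes differed with the dam's poly I:C injection whatever the pup had received. No gene passed the test, so some of the genes that differed in the same direction in both pup treatments are given as values. Tcra-v22.1, a T cell receptor alpha variable segment, was 3.26-fold lower on the array of the poly I:C dam in PBS pups and 3.68-fold lower in LPS pups, and Chmp1b2 was 3.39-fold and 3.19-fold lower. Apold1, an endothelial immediate early gene, was 1.66-fold and 2.15-fold lower. The 5.8S ribosomal RNA gene Rn5-8s was 2.38-fold and 2.39-fold higher. In limma's additive model, 0 of 17906 genes passed, and the smallest adjusted p was 0.485, for Tcra-v22.1 and Chmp1b2. An unadjusted p under 0.05 was found for 1065 genes, and without any effect a share of 0.05 of the 17906 would have one. Adjusted over the list alone, the haemoglobin gene Hbg1 rose among 15 erythroid and blood markers and Kl fell among 18 choroid plexus and ependymal markers, both named after their values were seen. Neither is a difference between measured levels throughout, since Hbg1 was not well above background on the arrays of PBS dams and Kl not on those of PBS pups, and 0 genes changed in the other lists. With normexp background correction and with the trended and robust variance prior, 3 genes were higher and 1 lower.

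Other genes with the same direction in PBS and LPS pups were found at both ends. Those higher in pups of the poly I:C dam were Spopfm2l2 (2.40-fold and 3.32-fold), Akr1c15 (1.81-fold and 3.24-fold), Mrgprb13 (1.73-fold and 2.06-fold), Rhox12 (1.71-fold and 3.71-fold), the steroid hydroxylase gene Cyp17a1 (1.71-fold and 1.77-fold), Krt77 (1.83-fold and 1.67-fold), Mfsd4b2l2 (1.66-fold and 11.7-fold), Bnip5 (1.64-fold and 1.70-fold) and Mapk15 (1.74-fold and 1.59-fold). Those lower were Il20ra (2.51-fold and 3.78-fold), Slc22a7 (2.14-fold and 2.87-fold), Ms4a6b (2.03-fold and 3.03-fold), Mmp28 (1.76-fold and 1.84-fold), Syne3 (1.63-fold and 1.94-fold) and the insulin-responsive glucose transporter gene Slc2a4 (2.72-fold and 1.63-fold). For Mapk15, Slc22a7, Ms4a6b and Syne3 a further probe of the gene above background went the other way. Across the 16843 genes the differences in PBS and LPS pups, which share no array, had Pearson's r of 0.0490 and Spearman's rho of 0.0796, with 4 genes at least 2-fold higher in both against 0.301 for independent lists and 6 lower against 0.0801. Pups of the same dam group may share a dam or litter, so this overlap cannot tell poly I:C from differences between dams or litters.

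In PBS pups, the array of the poly I:C dam had higher choroid plexus, meningeal and neutrophil markers, while the medians of the inflammatory lists lay nearer to 0. Ttr was 6.06 log2 higher, and the median of the choroid plexus and ependymal markers was 0.42 higher, with 15 of 18 members higher. The meningeal and fibroblast markers had a median of 0.80, with Ptgds, the prostaglandin D synthase of the meninges, 1.52 higher and Slc13a4 1.36 higher, and the neutrophil and monocyte markers a median of 1.07, with Np4 2.82 and S100a9 1.87 higher. The medians of the cytokines, the NF-kB targets and the interferon-stimulated genes were -0.06, -0.08 and 0.02. The first was 0.01 with normexp background correction and the last -0.04 with median scaling. Of 17073 genes measured on both arrays, 84 were at least 2-fold higher and 20 at least 2-fold lower, and 77 and 33 more had a bound of that size. Normexp background correction left 12 and 2, with medians of 0.27 for the choroid plexus and 0.45 for the neutrophil list, and with 1 array per group there is no p-value.

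In LPS pups, most of the inflammatory lists were lower on the array of the poly I:C dam. Cxcl1, a neutrophil-attracting chemokine, differed by -3.001 on the log2 scale, while Icam1 was 2.82-fold lower, Esm1, a product of activated endothelium, 3.33-fold lower and Mt1 2.89-fold lower. Il1b, Csf3 and Socs3 were 2.15-fold, 2.12-fold and 2.18-fold lower, whereas Isg15 and Gbp2 differed by -0.08 and -0.20. The list medians were -0.43 for endothelial activation, -0.40 for glucocorticoid-responsive genes, -0.39 for cytokines and chemokines, -0.37 for STAT3 and acute phase genes, -0.28 for NF-kB targets, -0.27 for interferon-stimulated genes and -0.22 for immediate early genes, each below all 10000 random lists. The MHC class I list had a median of -0.04 (9064 of 10000 random lists higher), and the toll-like receptor and inflammasome components -0.18 (9986 of 10000 higher), which was 0.00399 with normexp background correction. On the same array the choroid plexus and ependymal markers had a median of -0.40 and the meningeal and fibroblast markers of -0.36, the neutrophil and monocyte markers of 0.05. Of 17366 genes measured on both arrays, 66 were at least 2-fold higher and 104 at least 2-fold lower, and 109 and 62 more had a bound of that size. Normexp background correction left 9 and 11, with medians of -0.21 for cytokines and chemokines, -0.20 for STAT3 and acute phase genes, -0.16 for NF-kB targets, -0.15 for interferon-stimulated genes, -0.05 for immediate early genes and -0.20 for the choroid plexus list, and there is no p-value for this difference.

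**Figure D3:**
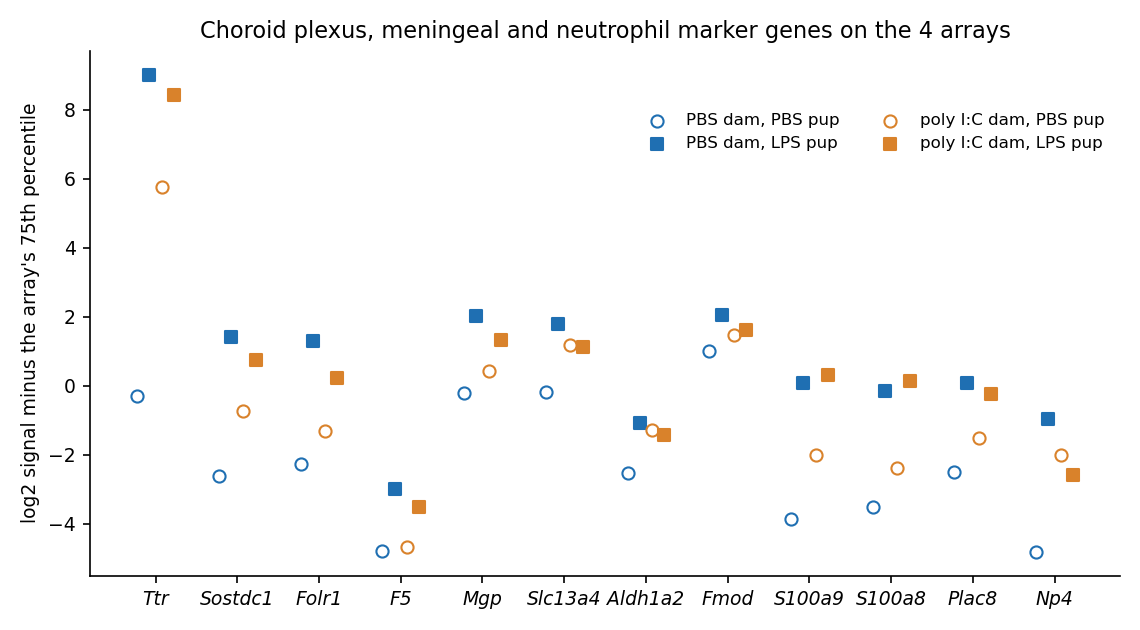
Log2 signal minus the 75th percentile of the array for 12 marker genes of choroid plexus, meninges and neutrophils, with 1 point per array. Ttr lies at -0.29 on the array of the PBS pup of the PBS dam and at 9.02, 5.77 and 8.44 on the arrays of the PBS dam and LPS pup, the poly I:C dam and PBS pup and the poly I:C dam and LPS pup.

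The last comparison asked whether the LPS difference itself depended on the dam's treatment. Most LPS-induced genes differed less in pups of poly I:C dams. Among 190 genes measured on all 4 arrays with a mean LPS difference of at least 2-fold, the median was 1.999 in pups of PBS dams and 1.35 in pups of poly I:C dams, and 159 of the 190 had the smaller difference in pups of poly I:C dams. The glucocorticoid-responsive genes had a median of -0.66 for the difference of LPS effects (23 of 26 members negative), endothelial activation genes -0.39 (18 of 22), the cytokines and chemokines -0.26 (20 of 30) and the interferon-stimulated genes -0.21 (31 of 43). The toll-like receptor and inflammasome components were evenly split, with a median of -0.05 (11 of 22) that was 0.00108 with normexp background correction. Choroid plexus and ependymal markers had -0.89 (16 of 18) and meningeal and fibroblast markers -1.16 (16 of 17).

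The genes with the most negative difference were Ttr (-6.64), Np4 (-4.45), the class I gene RT1-T24-3 (-2.79), C2cd4a (-2.68), Sostdc1 (-2.55), Upk1b (-2.39), Foxd2 (-2.34), the imprinted RNA gene H19 (-2.34), the lens crystallin gene Crygb (-2.25) and Defa10 (-2.21). For Foxd2 a further probe went the other way. Among the most positive were Lcp2 (3.86), an adaptor of immune receptor signalling, Mfsd4b2l2 (2.81), the sialyltransferase gene St8sia6 (2.73), the olfactory receptor gene Or11m3 (2.57), Otulinl (1.98), Tgm7 (1.91), Ano5 (1.86), Zfp133 (1.76) and Airim (1.72). For 98 genes the difference was at least 2-fold positive and for 243 at least 2-fold negative. Halved to the scale of the main effects, its SD over genes was 0.174, against 0.302 for LPS and 0.183 for poly I:C. No residual degree of freedom is left to test it, and normexp background correction left 11 and 34 genes, with medians of -0.13 for interferon-stimulated genes and -0.48 for the choroid plexus list, and the restriction to genes within 0.5 log2 on both PBS pup arrays left 49 and 86.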

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

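The tests of the choroid plexus and meningeal markers and of blood vessel markers were chosen after the results were seen.

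The LPS difference went opposite ways in the dam groups, by at least 2-fold each way, for 2 of the genes named for this difference and given here, and by a median of at least 0.1 log2 each way for 2 gene lists. Other genes and lists went opposite ways by less, and none of these differences could be tested. Lcp2 was 2.82 lower after LPS in pups of PBS dams and 1.04 higher in pups of poly I:C dams on the log2 scale, a difference of 3.86. Upk1b was 1.33 higher and 1.06 lower, a difference of -2.39. The 17 meningeal and fibroblast markers had medians of 0.83 and -0.26, a difference of -1.10, and the 21 hindbrain identity genes -0.13 and 0.10, a difference of 0.23. Across the alternatives the hindbrain medians ranged from -0.17 to -0.09 and from 0.04 to 0.11, so they did not always reach 0.1 each way. Outside the named genes, 8 of 4637 unnamed probes well above background on all 4 arrays were at least 2-fold higher after LPS in both dam groups.

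Choroid plexus and meningeal markers differed between the 4 arrays. LPS alone is argued against for the meningeal genes, since 3 of 17 members were higher after LPS in pups of poly I:C dams (exact binomial 95% interval 3.80% to 43.4%) and the PBS pup arrays differed by a median of 0.80. For the choroid plexus genes, LPS cannot account for the difference between the PBS pup arrays, since those pups received none. Their median difference was 0.42, and Ttr lay at -0.29 for the PBS dam and 5.77 for the poly I:C dam. Whether LPS alone caused the LPS difference of 1.67 stays open, because 0.42 is below the bound of 50% of it that was set first. On the PBS pup array of the poly I:C dam 83.3% of 18 members were higher (15, interval 58.6% to 96.4%), which a bound on this share, tried after the values were seen and then dropped, would have counted against LPS alone, although members of a list on 1 pair of arrays are not independent. Different amounts of choroid plexus in the dissections may explain the pattern. Of 14 choroid plexus and ependymal members other than Ttr, 71.4% (10, interval 41.9% to 91.6%) were lowest and highest on the same arrays as Ttr. Any cause acting on the whole tissue could give such a share, so it does not favour the dissections. A poly I:C effect on the choroid plexus stays open and untested.

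The LPS-induced genes differed less after LPS in pups of poly I:C dams. Compressed signals on that LPS array are argued against by 7 spike-in controls, whose log2 signals had a slope of 0.997 (95% interval 0.984 to 1.01) against the PBS dam's LPS array, while the slope of the LPS effects of 182 induced genes was 0.724. Fewer blood vessels stay open. The median of 19 vessel markers between the LPS arrays was -0.0896 (bootstrap 95% interval -0.16 to 0.08), above the -0.41 of the induced genes. However, 5 of these markers fell with LPS adjusted over the list alone, so their levels do not measure vessels apart from the LPS response. Less choroid plexus and meninges on that LPS array stays open, since their markers had medians of -0.40 and -0.36 there, and the median of -0.32 (interval -0.51 to -0.18) for 52 induced genes equal on both PBS pup arrays does not bear on genes that these tissues express only after LPS. A weaker response after poly I:C to the dam and a difference between single animals or injections both stay open, untested with 1 array per group.

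Some genes stood apart on 1 array only. For 96 genes 1 array lay at least 1 log2 from the nearest of the others, which lay within 0.5 of each other, and 6 of them were RT1 genes of the polymorphic MHC region, against 0.209 for an even draw. All 6 were high on an LPS array. RT1-A3, RT1-A1, RT1-CE13 and RT1-CE15 stood out for the poly I:C dam, RT1-T24-4 and RT1-Da for the PBS dam. Related genes on the same array are not independent draws, and a response to LPS on that array stays open. On the array of the PBS pup of the PBS dam, where Ttr was lowest too, 30 of the 96 were low, among them the meningeal gene Aldh1a2, and 3 were high. A sequence or copy difference under single probes between outbred animals cannot be told apart from a difference in transcript level, because few of these genes have another probe. Of 14 further probes, 64.3% showed at least 50% of the deviation (exact binomial 95% interval 35.1% to 87.2%), beside 74.5% of 51 further probes of LPS-induced genes.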

How the results depend on the processing

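The restriction to genes within 0.5 log2 on both PBS pup arrays was chosen after the data were seen. Counts stayed within 1.5 times the reported ones with the authors' table, outlier spots kept and quantile normalization in every comparison, and the cause of the differences below was not tested unless stated.

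For the LPS main effect (30 genes higher, 1 lower), normexp background correction gave 318 and 70, a trended and robust variance prior 220 and 50, median scaling 77 and 4, no term for the other treatment 76 and 10, no filter on dim probes 0 and 0, and the restricted genes 9 and 0. The last pair is not the number of called genes that meet the restriction, since Srms, the 1 gene lower, meets it too. With genes well above background on all 4 arrays 2 were lower. Leaving out 1 array, with the lone array assumed to vary like the others and with no term for the other treatment, gave between 1 and 33 higher and 0 lower. For the poly I:C main effect (0 and 0), normexp background correction and the trended and robust prior each gave 3 higher and 1 lower, and leaving out 1 array gave 0 to 0.

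Without a filter on dim probes, which adds genes near background, counts higher and lower were 1045 and 572 for LPS in pups of PBS dams, 961 and 755 in pups of poly I:C dams, 890 and 471 for poly I:C in PBS pups, 897 and 729 in LPS pups and 1168 and 1450 for the difference between the LPS effects. At 1.5-fold they were 739 and 349, 427 and 313, 393 and 146, 323 and 401, and 490 and 825. With normexp background correction, whose offset of 50 draws dim genes together, they were 126 and 6, 80 and 4, 12 and 2, 9 and 11, and 11 and 34. The restricted genes gave 199 and 40, 134 and 23, and 49 and 86 for both LPS effects and their difference, with fewer genes counted. The median of a gene's probes gave 30 lower for poly I:C in PBS pups. It turned the mean poly I:C difference of Mapk15 to -0.0177.

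Of 160 list medians, 80 moved by more than the spread of random lists with normexp background correction, 41 with median scaling, 23 with quantile normalization and 0 with the authors' table. Of 40 values of named genes without a test, normexp background correction moved 39. Well above background on all 4 arrays is the reported setting for the difference between the LPS effects. Slide as a block was not run, since all 4 arrays share 1 slide. No paired analysis was possible because each group has 1 array. Between 2 arrays, a gene well above background on 1 of them only has a bound.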

Other observations

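Genes of myelin, sterol synthesis and cell division had small median differences, mixed in some comparisons. The 22 oligodendrocyte and myelin genes had a median of -0.23 on the array of the poly I:C dam in PBS pups, with 1 member higher, and -0.07 in LPS pups, with 6 members higher. Opalin, a membrane protein of myelinating cells, was 0.48 and 0.59 lower, and Mal 0.32 and 0.37 lower. LPS differences of this list were -0.16 in pups of PBS dams and -0.04 in pups of poly I:C dams. The 24 cholesterol synthesis genes had LPS medians of -0.20 and -0.10, both below all 10000 random lists, with 3 and 4 members higher. On the array of the poly I:C dam 3 of 24 members were higher in PBS pups (median -0.13, below all 10000 random lists) and 12 of 24 in LPS pups (median -0.01). In the myelin and cholesterol lists, the LPS median in pups of PBS dams and the poly I:C median in PBS pups subtract the same array. That array is the one of the PBS dam and PBS pup, so these 2 medians are not separate findings. The 14 oligodendrocyte precursor markers had LPS medians of -0.17 and -0.10. The 26 cell cycle genes had -0.24 and -0.06, and in LPS pups they were 0.15 higher on the array of the poly I:C dam, with 25 of 26 members higher and 9988 of 10000 random lists lower. In limma's fit 0 members of these 4 lists passed for LPS or poly I:C by either adjustment.

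The 22 monoaminergic neuron genes had LPS medians of 0.25 in pups of PBS dams, above all 10000 random lists, and 0.01 in pups of poly I:C dams. Their median for poly I:C in PBS pups was 0.21, above all 10000 as well. Both higher medians subtract the array of the PBS dam and PBS pup, so they are not separate findings. In LPS pups, without that array, the poly I:C median was -0.03. With normexp background correction the higher medians were 0.02 and 0.07. Gch1, the first enzyme of tetrahydrobiopterin synthesis, was 1.75 and 0.84 higher. The median of 0.01 was below 0 with normexp background correction. The 33 respiratory network and neuropeptide genes had 0.10, above 9997 of 10000 random lists, and 0.03, led by the proton-sensing receptor gene Gpr4 at 1.29 and 0.20. The 33 genes of excitatory, inhibitory and cholinergic transmission had medians of -0.00019 and 0.03, and 20 cerebellum and forebrain markers -0.14 and -0.12, of which 1, the GABA receptor gene Gabra6, fell for LPS adjusted over the list alone. The hindbrain identity genes were higher in 19 of 21 cases on the LPS array of the poly I:C dam, with a median of 0.12. The 15 erythroid and blood markers had LPS medians of 0.57 and 0.20, the alpha-globin gene Hba-a2 being 0.88 and 0.21 higher, and a median of 0.28 between the PBS pup arrays. The 0.57 and 0.28 subtract the same array too, and in LPS pups the poly I:C median was -0.09. The 7 perivascular macrophage markers had 0.20 and -0.02, with Clec10a at 2.41 and 1.29. Of these, 1 rose over all genes, Cd163 (adjusted p = 0.0364, limma), named after its values were seen, and 2 adjusted over the list alone. Cd163 was well above background on neither PBS pup array, at -6.49 and -6.99, so the size of its rise is not exact. The 6 lymphocyte markers had -0.05 and 0.07, and the 17 heat shock and hypoxia genes 0.04 and 0.05, of which 3 rose adjusted over the list alone and 0 over all genes, with the vasodilator peptide gene Adm 1.48 and 1.38 higher. The first of the last pair was below 0 with median scaling.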
